A study of Mus musculus with 30 samples.

How the data were processed

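The series holds mRNA sequencing of 30 mouse samples in 10 groups of 3, from 3 experiments. The first compared colon epithelium of Smad4+ control mice with that of mice the submitters named Smad4ΔLrig1 (Smad4 knockout). The second used colonocytes in culture, labelled IMCfl/fl Smad4+, left untreated or given TNF, TGFB1 with BMP2, or all 3 ligands. The third used colonoids, which are epithelial organoids grown from colon, of the lines L42, L43 and L46, given vehicle, TNF (100 ng/mL), TGFB1 (3 ng/mL) with BMP2 (10 ng/mL), or all 3. Ligand doses and the length of treatment of the colonocytes are not given in the sources used here. The series description calls the samples of a group biological replicates; what separates the replicates of the colonocytes is not given in the sources used here, so their p-values measure the spread between these cultures. Per the series description, RNA was isolated with an RNeasy kit and libraries were made with a TruSeq Stranded mRNA kit, then read as 51 bp single-end reads (colon, 32 to 37 M stated) or 75 bp paired-end reads (colonocytes, 26 to 50 M stated, and colonoids, 50 to 72 M stated).

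The authors deposited 7 tables, 1 per comparison of 2 groups, each with 6 library columns. The deposited library columns hold a signal in CPM, reads scaled to a common effective library size and not to the plain read total. Each table was normalized on its own, so a library that stands in 2 tables has slightly different CPM in them. The deposited tables also hold the authors' log2 fold change and average log2 CPM per gene, and the authors' p-value and false discovery rate, per the file headers. Per the submitters' processing notes, the tools were CASAVA, bcl2fastq 2.16, TopHat2 2.1.0, SAMtools 1.3.1, HTSeq 0.5.4p5 and edgeR 3.4.2, with the genome build mm10; the role of each and the strand setting of the counting are not given in the sources used here. Reads of genes that overlap on opposite strands, or of near-identical paralogs, can therefore not be assigned with certainty. The tables list 11608 genes for colon epithelium, 11588, 11628 and 11573 for colonocytes (TNF, TGFB1 with BMP2, and TGFB1 with BMP2 under TNF) and 11688, 11665 and 11613 for colonoids in the same order. Genes below the authors' expression filter are not in a table and were not tested in it; in the list medians of levels, they were counted as 0.

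The low values of every library column were whole multiples of the value of 1 read, so whole reads were recovered. Of the listed values, 100% came out within 0.05 of a whole read in all 7 tables, and the reads recovered for a library that stands in 2 tables were the same for 100% of the genes in both. Recovered reads over listed genes came to 23.2 to 28.6 M per library in colon epithelium, 21.6 to 42.9 M in colonocytes and 42.2 to 61.7 M in colonoids. Replicate pairs within a group differed by more than counting noise, with a chi-square per gene of 7.66 to 61.7 in colon epithelium (6 pairs), 4.31 to 13.2 in colonocytes (12 pairs) and 39.6 to 288 in colonoids (12 pairs). Separate preparations of 1 culture would exceed counting noise as well, so this does not show that libraries are independent. Each library was counted as 1 replicate because the series description calls them biological replicates.

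Samples were grouped by the submitters' titles. The design, most alternative settings, the 22 gene lists and the rule for named genes were chosen before the data were examined. An edgeR quasi-likelihood test over all 12 libraries of a culture system had been planned for counts. Because the tables hold normalized values, the main test was limma (eBayes with a mean-variance trend, two-sided) on log2(CPM + 1) of genes with a mean CPM of at least 1, within the 6 libraries of each table, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on this log2(CPM + 1) scale, which understates the change of genes with low values. The 2 interaction terms (whether the TGFB1 and BMP2 effect differed with TNF) needed all 12 libraries of a system, so the recovered reads of the genes listed in all 3 tables were joined, scaled by TMM and tested the same way. As an added alternative, the count test (edgeR quasi-likelihood on the recovered reads) called 4592 genes for the knockout, 767, 3601 and 3752 for colonocytes and 16, 6378 and 6002 for colonoids, in the order used above. The authors' deposited tables hold a false discovery rate under 0.05 for 4695, 1021, 3784, 3954, 88, 5191 and 4991 genes in the same order. Versions were R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.

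Gene lists were tested with camera (preset correlation 0.01, at least 5 members tested, Benjamini-Hochberg adjustment over the lists of a comparison), and again with a correlation estimated from the residuals. The lists were NF-kB and TNF targets, chemokines, other cytokines, TGFB targets, BMP targets, interferon-stimulated genes, antigen presentation, epithelial defence, goblet cell markers, absorptive colonocyte markers, stem cell and Wnt genes, enteroendocrine markers, tuft cell markers, cell cycle genes, mesenchymal transition and matrix genes, epithelial junction and keratin genes, lymphocyte and plasma cell markers, myeloid markers, pan-leukocyte markers, stromal and muscle markers, endothelial markers, and dissociation and stress genes. With the estimated correlation, 5 of the 59 camera calls held: NF-kB and TNF targets, chemokines and antigen presentation for TNF in colonocytes, NF-kB and TNF targets for TNF in colonoids, and chemokines for the interaction in colonocytes. With the replicate block as well only the last held. The adjusted p of the other 4 by camera was 0.0827, 0.0827, 0.135 and 0.208 there, in the order given. A list's median, mean and camera direction differed in sign in 23 of 144 list tests, of which 0 were camera calls. Calls were compared between systems by Fisher's exact test (two-sided) over the genes tested in both. The effect of TGFB1 and BMP2 on genes induced by TNF was tested with camera in each culture system on the genes called higher with TNF in the other system, which share no library with the effect tested.

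Genes were named by a fixed rule: Smad4 and Ccl20 in every comparison, the 6 largest rises and 6 largest falls among genes with an adjusted p under 0.05, a mean of at least 1 log2 CPM and no overlap between the groups' values, up to 4 members of each list with the smallest adjusted p, and the 4 largest each way per interaction. Predicted genes and antigen receptor segments were left out of the largest rises and falls. Some genes that met the rule are not reported here. Positions are from GENCODE vM21 on mm10, which holds 250 of the 254 named genes under the same symbol.

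Groups share replicate numbers (colonoids, the line), so samples with the same number were checked for shared deviations from their group means. The correlations were above 0.1 for all 3 pairs in TNF colonocytes (0.27 to 0.52) and in TGFB1 and BMP2 under TNF in colonocytes (0.16 to 0.41). The colonoid samples of a line come from the same line, with correlations of 0.74 to 0.89, 0.31 to 0.59 and 0.28 to 0.59 for TNF, TGFB1 with BMP2, and TGFB1 with BMP2 under TNF, and of 0.27 to 0.94 over all 12 libraries. These fits were taken as paired, and the value with a replicate block stands beside a result only where it changed a call or moved a count by over 1.5 times. Counts of list members called are from the fits without the block. Alternatives were the replicate block, a pseudocount of 0.1, no filter on low values, DESeq2 size factors, total listed reads as the only scaling, edgeR and DESeq2 on the recovered reads, a fit over all 12 libraries of a system, other camera settings and fry, and each library left out in turn. Leave-outs were fitted without the block. In colonoids they therefore also left the lines unequal between the groups.

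The test was run first on simulated data with the real means, depths and spread and 200 genes changed by known folds, 50 per fold. A change of 2-fold was recovered for 86% of changed genes in the knockout setting, for 94%, 98% and 96% in the colonocyte comparisons (TNF, TGFB1 with BMP2, and the latter under TNF), and for 70%, 34% and 60% in the colonoid comparisons in the same order. A change of 4-fold was recovered for 98%, then 100%, 100% and 98%, then 94%, 78% and 94%. For the interactions, 92% (colonocytes) and 14% (colonoids) of 2-fold and 100% and 68% of 4-fold changes were recovered. False calls made up 3.77% to 11.8% of all calls, and their share was under the threshold of 0.05 in the knockout setting only. Of 200 unchanged lists, 4 had a camera p under 0.05. Genes were simulated independently and the unchanged lists drawn at random, so this does not test camera on lists of correlated genes. Only 200 genes were changed in a simulation, whereas the real comparisons called 16 (TNF in colonoids) to 6596 genes (TGFB1 with BMP2 in colonoids). The Benjamini-Hochberg cut-off depends on that number, so the shares recovered do not carry over to the real tests.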

Results

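Gene expression was measured by mRNA sequencing in mouse colon epithelium with and without Smad4, and in colonocytes and colonoids given TNF, TGFB1 with BMP2, or all 3 ligands. Smad4 is the shared signal transducer of the TGFB and BMP pathways, and TNF is an inflammatory cytokine that acts through NF-kB. The series concerns Smad4 signalling and the induction of Ccl20, a chemokine that attracts cells bearing the receptor Ccr6. Each of the 10 groups had 3 libraries with 21.6 to 61.7 M recovered reads, and values are CPM given as mean ± SD (n = 3) unless stated. Ccl20 lies on chromosome 1 at 83116766 to 83119167 on the plus strand, and Smad4 on chromosome 18 at 73639009 to 73703780 on the minus strand of mm10, both annotated as protein-coding genes.

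In the colon epithelium, Smad4 stood at 132, 148 and 152 CPM in the control libraries and at 47.8, 59.2 and 46.1 CPM in the knockout libraries. It fell by 1.49 on the log2 scale (SE 0.12, adjusted p = 7.01e-05 by limma with Benjamini-Hochberg adjustment), which left 35.4% of the control level. Ccl20 was 1.46 ± 0.275 CPM in controls and 4.64 ± 2.15 CPM in the knockout, a rise of 1.13 (SE 0.24, adjusted p = 0.00559 by limma), with all 3 knockout libraries (2.85, 7.03 and 4.04) above the highest control (1.77). Id3, an inhibitor of basic helix-loop-helix factors that BMP signalling induces, went from 119 ± 13 to 3.30 ± 0.549 CPM, the largest fall of the named genes (fell by 4.81 on the log2 scale, adjusted p = 7.88e-08 by limma). It lies on chromosome 4 at 136143497 to 136145755.

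**Figure D1:**
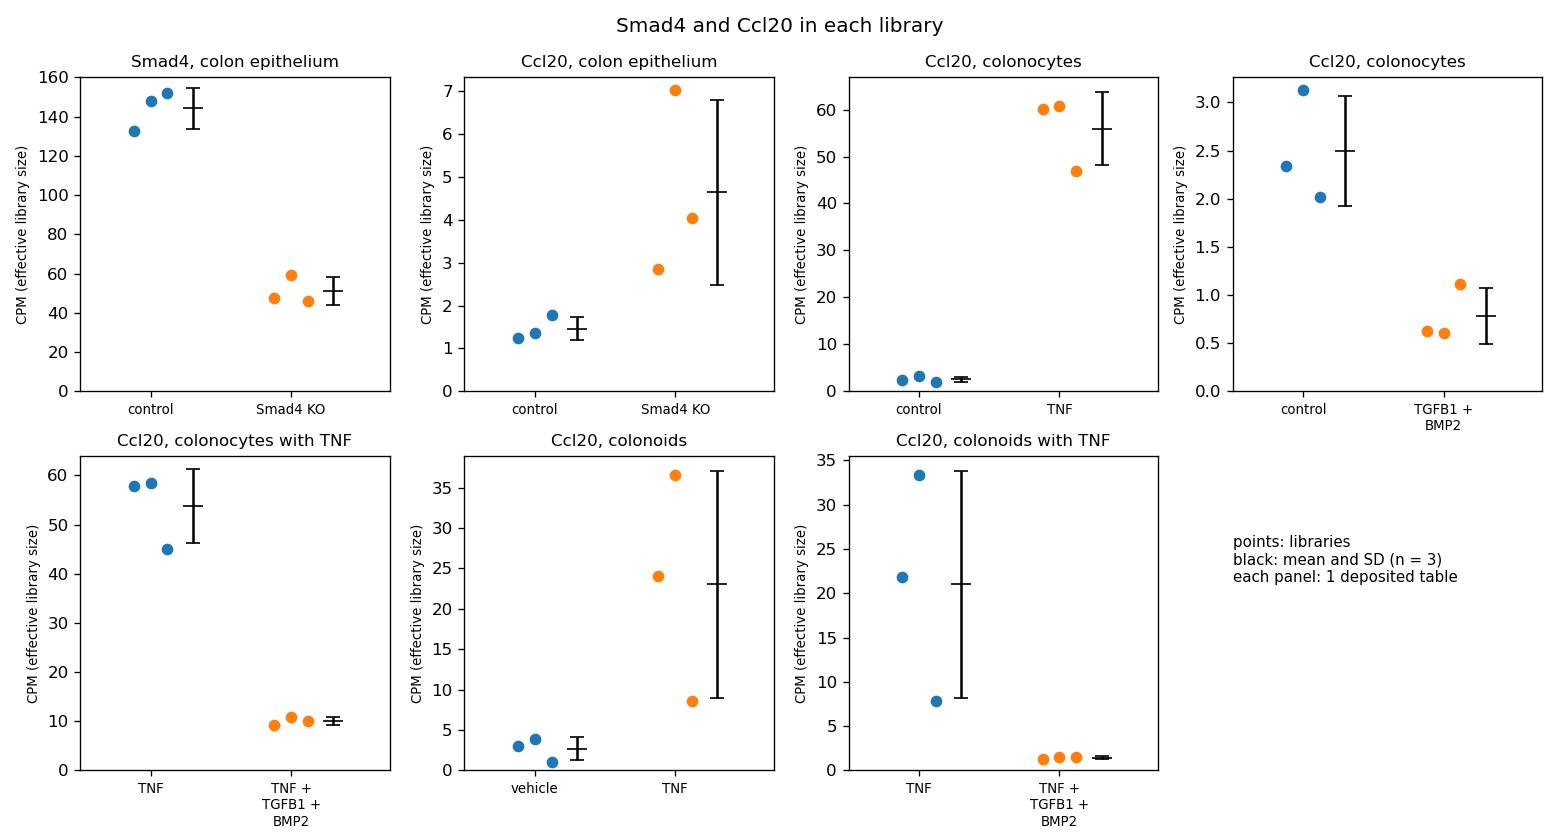
CPM (y axis) of Smad4 and Ccl20 in single libraries by group, with the mean and SD (n = 3) in black; each panel is 1 deposited table. Ccl20 averaged 2.54 CPM in control and 56.0 CPM in TNF-treated colonocytes, and 53.7 CPM with TNF against 10.1 CPM with TNF, TGFB1 and BMP2.

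Other large falls in the knockout were in Mptx1, a mucosal pentraxin (593 ± 213 to 24.2 ± 12.4 CPM), Mal, a lipid raft protein of apical transport (196 ± 23.6 to 7.84 ± 2.58), and the sulfotransferase Sult1a1 (660 ± 103 to 65.4 ± 11.6). Sct, the hormone secretin, fell too (17.9 ± 4.16 to 1.16 ± 0.270). Large rises were in AI747448 (77.6 ± 5.14 to 717 ± 148 CPM) and Lrg1, a secreted glycoprotein linked to inflammation (7.71 ± 0.752 to 71.5 ± 24.1). They were followed by the homeobox gene Hoxd13 (6.69 ± 1.44 to 41.8 ± 16.4), the retinol dehydrogenase Dhrs9 (4.67 ± 0.601 to 27.9 ± 5.23) and H60c, a ligand family member of the receptor NKG2D (1.23 ± 0.274 to 10.0 ± 2.11). Aadac also fell (50.3 ± 21.6 to 7.71 ± 7.44 CPM), a call that was lost with edgeR on the recovered reads. Adjusted p by limma lay between 1.56e-06 (Mal) and 0.00296 (Aadac) for these genes.

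Of 8 measured BMP targets, 6 fell and 1 rose, with the same counts adjusted over the list alone. Id1 fell from 223 ± 16.2 to 49.2 ± 4.07 CPM, Id2 from 25.4 ± 2.73 to 7.81 ± 1.46, and the inhibitory Smad6 from 20.2 ± 1.20 to 6.18 ± 1.18. Camera placed the BMP list lower (adjusted p = 0.000494, and adjusted p = 0.142 with an estimated correlation). The 18 measured TGFB targets went both ways, with 7 higher and 5 lower (7 and 5 adjusted over the list alone; camera adjusted p = 0.725). The cell cycle inhibitor Cdkn1a fell from 182 ± 10.3 to 75.1 ± 1.64 CPM and the matrix protein gene Tgfbi from 12.5 ± 0.698 to 3.27 ± 0.785, while the feedback genes Skil and Pmepa1 rose from 49.3 ± 5.21 to 107 ± 6.34 and from 15.7 ± 0.304 to 41.1 ± 6.73.

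Goblet, absorptive and enteroendocrine lists moved lower in the knockout by camera, though not with an estimated correlation. Of 15 goblet cell markers, 9 fell and 1 rose (9 and 1 adjusted over the list alone; camera adjusted p = 0.00715, and adjusted p = 0.606 with an estimated correlation). Examples are the mucus proteins Zg16 (2122 ± 437 to 541 ± 61.2 CPM) and Fcgbp (1240 ± 100 to 528 ± 145) and the trefoil factor Tff3 (354 ± 37.4 to 134 ± 21.6). Of 20 absorptive colonocyte markers, 12 fell and 3 rose (13 and 3 adjusted over the list alone; camera adjusted p = 0.0105, and adjusted p = 0.606 with an estimated correlation). Guca2a, the precursor of guanylin, went from 761 ± 57.8 to 230 ± 89.7 CPM, and the bile acid transporter subunit Slc51a from 68.0 ± 3.76 to 19.1 ± 6.73. Of 13 enteroendocrine markers 9 fell and 0 rose (9 and 0 adjusted over the list alone; camera adjusted p = 0.000494, and adjusted p = 0.142 with an estimated correlation). They included neurotensin (Nts, 10.0 ± 1.71 to 1.82 ± 0.348), Insl5 (31.6 ± 0.641 to 13.6 ± 2.12) and the proglucagon gene Gcg (107 ± 9.08 to 56.1 ± 9.29). Stem cell and Wnt genes went both ways, 6 higher and 6 lower of 19 (6 and 6 adjusted over the list alone; camera adjusted p = 0.998). Smoc2 rose from 37.4 ± 1.70 to 80.1 ± 5.33 CPM and Ascl2, a stem cell transcription factor, fell from 9.65 ± 1.59 to 2.04 ± 0.785.

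Inflammation and defence genes rose in part. Of 14 other cytokines, 8 rose and 2 fell (8 and 2 adjusted over the list alone; camera adjusted p = 0.0105, and adjusted p = 0.224 with an estimated correlation). Among them were the epidermal growth factor receptor ligands Areg (6.53 ± 0.972 to 18.5 ± 1.15 CPM) and Ereg (0.989 ± 0.273 to 4.30 ± 1.09) and Il18 (64.6 ± 12 to 134 ± 25.3). Of 26 interferon-stimulated genes 15 rose and 2 fell (17 and 3 adjusted over the list alone; camera adjusted p = 0.00471, and adjusted p = 0.606 with an estimated correlation). Ifit2 stood at 12.8 ± 0.856 in controls and 53.2 ± 9.16 in the knockout. Of 19 epithelial defence genes 11 rose and 3 fell (11 and 3 adjusted over the list alone; camera adjusted p = 0.0145, and adjusted p = 0.34 with an estimated correlation). The antimicrobial lectin Reg3b went from 2476 ± 94.2 to 6871 ± 1860 CPM and the protease inhibitor Slpi from 9.45 ± 1.54 to 33.3 ± 1.87. Of 12 chemokines, 5 rose and 1 fell (5 and 1 adjusted over the list alone; camera adjusted p = 0.229). Cxcl5 stood at 0.145 ± 0.0622 and 3.10 ± 2.21 CPM and Ccl25 at 8.22 ± 2.69 and 2.36 ± 0.203. NF-kB and TNF targets went both ways, 5 higher and 6 lower of 27 (5 and 6 adjusted over the list alone; camera adjusted p = 0.998). The complement gene C3 rose from 36.0 ± 1.05 to 97.4 ± 27.6 and the NF-kB subunit Relb fell from 36.6 ± 2.63 to 21.0 ± 1.81.

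Markers of other cell types gave no camera call in this comparison. Of 12 lymphocyte and plasma cell markers 1 rose and 4 fell (camera adjusted p = 0.525). The plasma cell gene Igj stood at 10.5 ± 4.85 in controls and 24.5 ± 2.67 CPM in the knockout and the T cell gene Cd3d at 4.68 ± 1.45 and 2.02 ± 0.275. Of 8 myeloid markers 1 rose and 1 fell (camera adjusted p = 0.998), and of 10 pan-leukocyte markers 0 rose and 1, Coro1a, fell (11 ± 2.90 to 5.52 ± 1.42; camera adjusted p = 0.533). The median log2 change was -0.18 for lymphocyte and plasma cell markers, -0.05 for myeloid markers and -0.16 for pan-leukocyte markers. Neither the 2 stromal and muscle markers nor the 1 endothelial marker measured passed the test. The remaining lists also gave no camera call: antigen presentation (1 rose and 4 fell of 17, adjusted p = 0.349), tuft cell markers (0 and 3 of 9, 0.5), cell cycle genes (5 and 2 of 25, 0.52) and mesenchymal transition and matrix genes (4 and 2 of 9, 0.533). The same held for junction and keratin genes (6 and 5 of 19, 0.787) and stress genes (2 and 3 of 13, 0.588). Counts adjusted over the list alone were the same for lymphocyte and plasma cell, myeloid, pan-leukocyte, tuft cell, mesenchymal and stress genes, and 1 and 3, 5 and 1, and 7 and 6 for antigen presentation, cell cycle, and junction and keratin genes. Among single genes, B2m, the light chain of class I antigen presentation, rose from 1623 ± 204 to 2952 ± 490 CPM.

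In all, 4611 of 11607 genes passed the limma test in the knockout, 2300 higher and 2311 lower. Without control replicate 2 the count was 2723 and without knockout replicate 2 it was 2709.

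TNF raised inflammatory genes in the colonocytes. Ccl20 went from 2.54 ± 0.580 to 56.0 ± 7.84 CPM (log2 change 4.01, SE 0.13, adjusted p = 2.05e-08 by limma with Benjamini-Hochberg adjustment), the largest rise among the named genes. The monocyte-attracting chemokines Ccl2 and Ccl7 went from 75.9 ± 6.38 to 1115 ± 116 CPM and from 10.2 ± 0.213 to 106 ± 5.20, and Cxcl10, which attracts T cells, from 17.8 ± 2.42 to 151 ± 26.9. The NF-kB inhibitor gene Nfkbie went from 4.40 ± 0.309 to 35.1 ± 5.20 and the guanylate-binding protein gene Gbp5 from 2.02 ± 0.455 to 18.7 ± 4.07. Falls were smaller: the ephrin receptor Ephb3 went from 37.6 ± 4.07 to 22 ± 1.00 CPM (fell by 0.75 on the log2 scale), the pro-apoptotic Bmf from 4.91 ± 0.583 to 2.64 ± 0.452, Tnfrsf25 from 8.46 ± 0.400 to 4.85 ± 0.216 and Fam46c from 11.7 ± 1.95 to 6.82 ± 0.718. Gas1 and Sema6d were also among the largest falls (log2 changes of -0.88 and -0.72). Gas1 lost its call without control replicate 1 or 2 or TNF replicate 1 or 3, and Sema6d without control replicate 1 or 2. Smad4 was 121 ± 4.66 and 121 ± 1.95 CPM (log2 change 0.01, adjusted p = 0.959 by limma).

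Of 27 NF-kB and TNF targets in colonocytes, 24 rose and 0 fell with TNF (26 and 0 adjusted over the list alone; camera adjusted p = 8.46e-47, and adjusted p = 0.0363 with an estimated correlation). The inhibitors Nfkbia and Tnfaip3 went from 36.3 ± 3.29 to 174 ± 8.62 CPM and from 95.8 ± 12.1 to 370 ± 11.9. Of 11 chemokines 7 rose and 1 fell (8 and 1 adjusted over the list alone; camera adjusted p = 4.42e-14, and adjusted p = 0.0274 with an estimated correlation). Of 25 interferon-stimulated genes 21 rose and 0 fell (25 and 0 adjusted over the list alone; camera adjusted p = 2.32e-31, and adjusted p = 0.0765 with an estimated correlation). Gbp2 stood at 22.3 ± 2.91 and 84.2 ± 12.5 CPM and Ifit3 at 8.66 ± 1.81 and 30.4 ± 2.97. Of 15 antigen presentation genes 6 rose and 0 fell (7 and 0 adjusted over the list alone; camera adjusted p = 5.52e-07, and adjusted p = 0.0363 with an estimated correlation). The peptide transporter subunit Tap2 was among them (52.0 ± 2.17 to 73.4 ± 0.445). Of 13 BMP targets 0 rose and 5 fell (0 and 8 adjusted over the list alone; camera adjusted p = 4.88e-07, and adjusted p = 0.0652 with an estimated correlation). Id2 fell from 41.2 ± 2.09 to 26.4 ± 2.04.

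Smaller shifts came with TNF in 4 further colonocyte lists, each a camera call that was lost with an estimated correlation. Of 12 other cytokines 4 rose and 1 fell (camera adjusted p = 0.00118, and adjusted p = 0.0652 with an estimated correlation). Csf1, the macrophage growth factor, stood at 1038 ± 45.8 and 1842 ± 16.6 CPM. Of 21 TGFB targets 8 rose and 1 fell (0.00035, and adjusted p = 0.125 with an estimated correlation). The immediate early gene Junb stood at 103 ± 17.7 and 282 ± 33.8. Of 21 mesenchymal transition and matrix genes 3 rose and 0 fell (0.0011, and adjusted p = 0.133 with an estimated correlation). Of 15 dissociation and stress genes 4 rose and 0 fell (0.00118, and adjusted p = 0.0652 with an estimated correlation). Egr1 stood at 68.3 ± 3.28 and 113 ± 4.41. Counts adjusted over the list alone were the same in these 4 lists. The stem cell and Wnt list gave no camera call (3 rose and 1 fell of 12, 3 and 2 adjusted over the list alone; adjusted p = 0.528), although Lrig1, a regulator of growth factor receptors, rose from 43 ± 2.04 to 68.8 ± 2.39. Camera made no call for tuft cell markers (0 and 0 of 5, adjusted p = 0.18), cell cycle genes (0 and 0 of 25, 0.406), junction and keratin genes (1 and 0 of 10, 0.959), stromal and muscle markers (1 and 0 of 14, 0.643) or endothelial markers (0 and 0 of 5, 0.486). Of the lists too small to test, 1 of 3 epithelial defence genes rose (Saa3, 4.52 ± 0.633 to 13.5 ± 4.02) and no member of the goblet (2), absorptive (1), enteroendocrine (2), myeloid (3) and pan-leukocyte (1) lists passed the test by limma, and 0 lymphocyte and plasma cell markers were measured.

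The TNF test in colonocytes called 728 of 11586 genes, 534 higher and 194 lower, and 442 higher and 296 lower with total listed reads as the only scaling. With the replicate block the count was 2356 (1337 higher and 1019 lower). It was 442 and 399 without control replicates 1 and 2, 1216 without control replicate 3, and 424 and 439 without TNF replicates 1 and 2.

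TGFB1 with BMP2 moved 3513 of 11620 genes in colonocytes. Pdgfb, a mesenchymal growth factor, rose from 7.92 ± 0.883 to 66.6 ± 5.92 CPM (log2 change 2.92, adjusted p = 1.42e-10 by limma with Benjamini-Hochberg adjustment), and Snai1, a transcription factor of epithelial-mesenchymal transition, from 10.1 ± 0.550 to 81.1 ± 9.38 (2.89, adjusted p = 1.23e-10 by limma). The protease gene Adamts15 (0.315 ± 0.0561 to 8.07 ± 1.35), Sox8 (0.392 ± 0.112 to 8.03 ± 2.12), the chemerin receptor Cmklr1 (1.14 ± 0.134 to 12 ± 1.01) and Csdc2 (14.4 ± 2.51 to 88.5 ± 5.46) rose as well. Large falls were in Pcdh9 (fell by 1.90 on the log2 scale), Igfbp5 (125 ± 40.8 to 34.3 ± 10.9 CPM), Sdpr (140 ± 18.6 to 39.1 ± 2.93), the Wnt modulator Sfrp2 (36.5 ± 3.96 to 10.1 ± 0.217) and the TNF family ligand Tnfsf18 (fell by 1.71). Ccl20 fell from 2.49 ± 0.572 to 0.783 ± 0.288 CPM (fell by 0.97 on the log2 scale, SE 0.16, adjusted p = 0.00051 by limma). Smad4 was 119 ± 4.80 and 124 ± 5.26 CPM (log2 change 0.07, adjusted p = 0.388 by limma), and the sign of that value turned with total reads as the scaling.

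All 21 measured TGFB targets rose in colonocytes (21 adjusted over the list alone; camera adjusted p = 1.69e-22, and adjusted p = 0.0622 with an estimated correlation). The inhibitory Smad7, on chromosome 18 at 75367529 to 75395935, went from 40.3 ± 3.58 to 161 ± 10.8 CPM, and Pmepa1 from 239 ± 17.2 to 915 ± 50.1. Of 15 BMP targets 7 rose and 3 fell (7 and 3 adjusted over the list alone; camera adjusted p = 0.0201, and adjusted p = 0.555 with an estimated correlation). Smad6 rose from 28.5 ± 2.96 to 76.9 ± 14.0 and Zfp503 fell from 41.8 ± 6.03 to 22.9 ± 2.37. Of 21 mesenchymal transition and matrix genes 14 rose and 4 fell (14 and 5 adjusted over the list alone; camera adjusted p = 9.6e-05, and adjusted p = 0.0658 with an estimated correlation). Control medians were already 104 to 113 CPM here and 0.783 to 1.08 for junction and keratin genes. The membrane protease Mmp14 stood at 437 ± 9.02 and 1222 ± 40.1 CPM and the laminin chain Lamb3 at 2.01 ± 0.0944 and 12 ± 1.70. Of 11 chemokines 6 rose and 1, Ccl20, fell (7 and 1 adjusted over the list alone; camera adjusted p = 0.00102, and adjusted p = 0.0776 with an estimated correlation). Fractalkine (Cx3cl1) rose from 2.89 ± 0.319 to 10.3 ± 0.703. Of 13 stem cell and Wnt genes 9 rose and 1 fell (9 and 1 adjusted over the list alone; camera adjusted p = 0.00102, and adjusted p = 0.0776 with an estimated correlation). Ephb2 stood at 19.4 ± 1.31 and 45.5 ± 5.90.

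The other colonocyte lists gave no camera call with TGFB1 and BMP2. NF-kB and TNF targets went both ways (9 rose and 5 fell of 27, 10 and 5 adjusted over the list alone; adjusted p = 0.611). The TNF receptor Tnfrsf1b rose from 109 ± 9.25 to 238 ± 20.8 CPM and the adhesion molecule Vcam1 fell from 182 ± 13 to 113 ± 7.76. Other cytokines did too (3 and 4 of 10, 4 and 4 adjusted over the list alone; adjusted p = 0.773). Hbegf rose from 15.5 ± 0.626 to 65.4 ± 6.52 and the alarmin Il33 fell from 9.34 ± 2.76 to 3.73 ± 0.530. Of 14 stromal and muscle markers 4 rose and 3 fell (4 and 3 adjusted over the list alone; adjusted p = 0.773). The collagen gene Col1a1 rose from 2119 ± 145 to 2905 ± 182 and Col3a1 fell from 1167 ± 86.1 to 829 ± 8.76. Of 5 endothelial markers 1, Kdr, rose (3.79 ± 0.702 to 20.6 ± 0.463) and 2 fell (1 and 3 adjusted over the list alone; adjusted p = 0.773). The adjusted p was also 0.773 for interferon-stimulated genes (1 and 1 of 24), antigen presentation (1 and 0 of 15), cell cycle genes (2 and 2 of 25), junction and keratin genes (3 and 3 of 9) and stress genes (4 and 4 of 15), and it was 0.204 for tuft cell markers (3 and 0 of 6). Of the lists too small to test, 1 goblet marker rose and 1 fell of 2, 1 absorptive marker rose of 1, 1 pan-leukocyte marker fell of 1, and no member of 3 epithelial defence, 2 enteroendocrine or 3 myeloid genes passed the test by limma. The test called 3513 genes, 1848 higher and 1665 lower, against 1228 and 2896 with total listed reads as the only scaling.

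Colonocytes given all 3 ligands were compared with those given TNF alone. Ccl20 fell from 53.7 ± 7.53 to 10.1 ± 0.752 CPM (fell by 2.30 on the log2 scale, SE 0.10, adjusted p = 1.05e-08 by limma with Benjamini-Hochberg adjustment), the largest fall of the named genes. Tnfsf18 fell from 17.8 ± 1.91 to 2.92 ± 0.0622, Cysltr1, a leukotriene receptor, from 7.19 ± 0.682 to 1.66 ± 0.488, Sdpr from 119 ± 16.0 to 35.4 ± 2.58, Sfrp2 from 34.0 ± 3.12 to 10.1 ± 1.27 and Igfbp5 from 84.2 ± 19.6 to 26.6 ± 7.51. Snai1 rose from 11.8 ± 1.18 to 88.1 ± 12.7 CPM and Pdgfb from 24.2 ± 1.26 to 168 ± 18.4, and Sox8, Adamts15, Csdc2 and Cmklr1 rose by 2.44, 2.41, 2.32 and 2.30 on the log2 scale. Of 25 interferon-stimulated genes 0 rose and 13 fell (0 and 15 adjusted over the list alone; camera adjusted p = 2.16e-06, and adjusted p = 0.562 with an estimated correlation). Gbp5 fell from 18.0 ± 3.91 to 6.81 ± 1.70 and Gbp2 from 80.8 ± 12.1 to 40.6 ± 6.29. NF-kB and TNF targets went both ways, 4 higher and 6 lower of 27 (4 and 6 adjusted over the list alone; camera adjusted p = 0.315). The kinase gene Ikbke fell from 93.3 ± 2.91 to 50.8 ± 0.902. Of 12 chemokines 6 rose and 2 fell (6 and 2 adjusted over the list alone; camera adjusted p = 0.197). Ccl17 stood at 0.241 ± 0.114 and 2.70 ± 0.279 CPM. Smad4 was 117 ± 1.87 and 119 ± 6.81 CPM (log2 change 0.03, adjusted p = 0.714 by limma), and the sign of that value turned with total reads as the scaling.

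Of 21 TGFB targets under TNF, 20 rose and 0 fell (21 and 0 adjusted over the list alone; camera adjusted p = 9.51e-21, and adjusted p = 0.0716 with an estimated correlation). Smad7 went from 39.7 ± 3.47 to 154 ± 11.2 CPM. Of 14 BMP targets 8 rose and 2 fell (10 and 2 adjusted over the list alone; camera adjusted p = 0.0208, and adjusted p = 0.615 with an estimated correlation), and the call was lost without replicate 2 of the cultures given all 3 ligands (0.058). Of 22 mesenchymal transition and matrix genes 14 rose and 4 fell (16 and 4 adjusted over the list alone; camera adjusted p = 3.96e-05, and adjusted p = 0.25 with an estimated correlation). Of 11 stem cell and Wnt genes 7 rose and 1 fell (7 and 1 adjusted over the list alone; 0.00469, and adjusted p = 0.25 with an estimated correlation). Under TNF camera made no call for other cytokines (3 and 4 of 14, adjusted p = 0.988), antigen presentation (1 and 3 of 15, 0.138), tuft cell markers (3 and 0 of 6, 0.14), or cell cycle genes (4 and 7 of 25, 0.454). Nor did it for junction and keratin genes (4 and 2 of 10, 0.988), stromal and muscle markers (5 and 3 of 14, 0.472), endothelial markers (1 and 2 of 5, 0.988) or stress genes (4 and 4 of 15, 0.769). Of the lists too small to test, 2 of 3 epithelial defence genes fell, 1 of 2 goblet markers rose and 1 fell, 1 of 1 absorptive and 1 of 2 enteroendocrine markers rose, 1 of 1 pan-leukocyte marker fell and 0 of 3 myeloid markers passed the test by limma. The test called 3694 of 11567 genes, 1892 higher and 1802 lower, against 1268 and 3065 with total listed reads as the only scaling.

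The fall of Ccl20 with TGFB1 and BMP2 was larger under TNF in the interaction test over the 12 colonocyte libraries. Ccl20 averaged 2.47 ± 0.561 CPM in controls, 0.776 ± 0.282 with TGFB1 and BMP2, 54.3 ± 7.61 with TNF and 10.2 ± 0.762 with all 3. Its interaction was -1.34 on the log2 scale (SE 0.19, adjusted p = 0.0384 by limma with Benjamini-Hochberg adjustment), the 1 gene called of 11434, while 356 had an unadjusted p under 0.05. The call was lost with edgeR (log2 interaction -0.64, adjusted p = 0.999) and DESeq2 (-0.64, adjusted p = 1) on the recovered reads and with a pseudocount of 0.1 (-0.82). It was also lost without control replicate 1, without TNF replicate 1 or 2, without replicate 1 or 3 of all 3 ligands and without any 1 of the 3 replicates of TGFB1 with BMP2, with adjusted p by limma of up to 0.264. More genes were called in other settings: 13 with DESeq2, 10 without control replicate 3, 7 without TNF replicate 3 and 5 without replicate 2 of all 3 ligands. With the replicate block 30 genes were called, and Ccl20 had an adjusted p of 0.000768 by limma. The fit was not taken as paired because 17 of its 18 same-number pairs, and not all, correlated above 0.1. Chemokines as a list moved lower in the interaction (0 rose and 1 fell of 11, 0 and 4 adjusted over the list alone; camera adjusted p = 2.39e-11, and adjusted p = 0.00882 with an estimated correlation). Interferon-stimulated genes did too (0 and 0 of 24, 0 and 11 adjusted over the list alone; camera adjusted p = 9.3e-22, and adjusted p = 0.157 with an estimated correlation). So did NF-kB and TNF targets (0 and 0 of 27, 0 and 4 adjusted over the list alone; camera adjusted p = 4.12e-09, and adjusted p = 0.157 with an estimated correlation).

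In 2 further colonocyte lists the interaction was lower by camera but depended on single libraries. For 21 TGFB targets (0 called, 0 higher and 1 lower adjusted over the list alone) the adjusted p was 0.0222 (adjusted p = 0.411 with an estimated correlation), and the call was lost without control replicate 2, replicate 1 of TGFB1 with BMP2, TNF replicate 3 or replicate 3 of all 3 ligands (up to 0.299). For 15 antigen presentation genes (0 called, 0 adjusted over the list alone) it was 0.00848 (adjusted p = 0.157 with an estimated correlation), lost without replicate 3 of TGFB1 with BMP2 or TNF replicate 3 (up to 0.201). In the interaction camera made no call for other cytokines (10 genes, 0 higher and 3 lower adjusted over the list alone; adjusted p = 0.0815), BMP targets (13, 0.141), stem cell and Wnt genes (11, 0.63), tuft cell markers (5, 0.461), or cell cycle genes (25, 0.501). Nor did it for mesenchymal transition and matrix genes (21, 0.308), junction and keratin genes (9, 0.871), stromal and muscle markers (14, 0.461), endothelial markers (5, 0.501) or stress genes (15, 0.242). Smad4 had an interaction of -0.04 on the log2 scale (adjusted p = 1 by limma).

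The TNF test in colonoids called 16 genes by limma, 14 higher and 2 lower, and 718 with the line as a block, 439 higher and 279 lower. A fit over 12 libraries called 7, and 41 with the block. The ubiquitin-like Ubd rose from 2.28 ± 0.251 to 14.0 ± 0.735 CPM (log2 change 2.20, adjusted p = 0.00261 by limma with Benjamini-Hochberg adjustment), the class I-like H2-M2 from 0.579 ± 0.169 to 8.67 ± 3.69, the inducible nitric oxide synthase Nos2 from 10.9 ± 1.79 to 59.2 ± 13.7, Megf6 from 1.72 ± 0.254 to 9.92 ± 2.08 and Lix1l from 3.07 ± 0.296 to 11.7 ± 1.96. Tnfaip3 rose from 54.0 ± 7.36 to 161 ± 16.7 CPM, Nfkbia from 134 ± 7.22 to 373 ± 64.0, the apoptosis inhibitor Birc3 from 52.8 ± 0.727 to 96.6 ± 4.43 and Tnf itself from 20.4 ± 4.26 to 53.9 ± 6.56. The 2 falls were in the lipid droplet enzyme gene Hsd17b13 (17.5 ± 0.362 to 7.08 ± 0.666) and the glutathione transferase Mgst1 (90.7 ± 3.32 to 59.3 ± 2.52). Ccl20 was 3.07, 3.90 and 1.11 CPM with vehicle and 24.0, 36.6 and 8.57 CPM with TNF in lines L42, L43 and L46, higher in each line. Its log2 change was 2.58 (SE 0.53) with an adjusted p of 0.304 by limma, and of 1.97e-05 with the line as a block. Smad4 was 139 ± 6.92 and 135 ± 6.40 CPM (log2 change -0.04, adjusted p = 1 by limma).

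Of 28 NF-kB and TNF targets in colonoids, 3 rose and 0 fell with TNF (18 and 0 adjusted over the list alone; camera adjusted p = 2.42e-33, and adjusted p = 0.0158 with an estimated correlation). Chemokines (0 of 12, 6 adjusted over the list alone; camera adjusted p = 2.35e-12, and adjusted p = 0.0792 with an estimated correlation) and other cytokines (1 of 15, 7 adjusted over the list alone; 5.96e-09, and adjusted p = 0.0792 with an estimated correlation) moved higher. Antigen presentation (1 of 12, 4 adjusted over the list alone; 3.82e-09, and adjusted p = 0.0792 with an estimated correlation) and epithelial defence (1 of 12, 4 adjusted over the list alone; 1.27e-06, and adjusted p = 0.288 with an estimated correlation) did too. These counts of members called are from the fit without the line as a block. Ccl20, a chemokine, passed with the block, so 0 of 12 does not hold for chemokines in the paired fit. Goblet cell markers moved lower with 0 of 15 called (camera adjusted p = 0.00679, and adjusted p = 0.63 with an estimated correlation), a call lost without vehicle L42, vehicle L43 or TNF L46 (up to 0.695). TGFB targets moved higher with 0 of 20 called (1 adjusted over the list alone; 0.000859, and adjusted p = 0.617 with an estimated correlation), lost without vehicle L43 or TNF L46 (up to 0.234). Interferon-stimulated genes did so with 0 of 18 called (0.00766, and adjusted p = 0.617 with an estimated correlation), lost without vehicle L43 or TNF L42 (up to 0.578). These leave-outs had no block for the line, so a lost call can come from unequal lines. With all libraries and the block, the camera adjusted p for goblet, TGFB and interferon lists was 6.36e-09, 0.000262 and 0.00512. With the block and an estimated correlation it was 0.395, 0.208 and 0.496. Mesenchymal transition and matrix genes passed camera with the line as a block (0 of 11 called; adjusted p = 0.0062 against 0.147 without it), but not with the block and an estimated correlation (adjusted p = 0.384).

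With TNF in colonoids camera made no call for BMP targets (0 of 7 genes called, adjusted p = 0.458), absorptive markers (0 of 19, 0.74), stem cell and Wnt genes (0 of 21, 0.94), or enteroendocrine markers (0 of 13, 0.74). It made none for cell cycle genes (0 of 25, 0.684), junction and keratin genes (0 of 19, 0.929) or stress genes (0 of 14, 0.94). Member counts here are from the fit without the line as a block. Of the lists too small to test, 0 of 4 tuft cell, 1 lymphocyte and plasma cell, 4 myeloid, 3 pan-leukocyte, 2 stromal and 2 endothelial markers passed the limma test over all genes, and 1 myeloid and 2 pan-leukocyte markers were higher adjusted over the list alone. On the recovered reads edgeR and DESeq2 called 16 and 116 genes. The limma test called 16 of 11688, while 514 had an unadjusted p under 0.05. The counts were 5, 2 and 1 without vehicle L42, L43 and L46 and 4, 8 and 8 without TNF L42, L43 and L46, and of the named genes Ubd kept its call in all 6. These leave-outs had no block for the line and left the lines unequal between the groups.

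TGFB1 with BMP2 moved 6596 of 11633 genes in colonoids, and 4598 to 7603 when 1 library was left out. The treated L46 library stood apart, with a chi-square per gene of 172 and 288 against L42 and L43, which differed by 79.2. With all 3 ligands these values were 204, 253 and 59.8. Arg1, an arginase of the urea cycle, rose from 1.10 ± 0.408 to 126 ± 80.7 CPM (log2 change 5.61, adjusted p = 0.00168 by limma with Benjamini-Hochberg adjustment), the lipoxygenase Alox12 from 1.86 ± 0.666 to 144 ± 109, the acyl-CoA synthetase Acsbg1 from 7.16 ± 2.53 to 329 ± 97.8 and the transcription factor Onecut2 from 1.75 ± 0.632 to 96.2 ± 48.2. The polymeric immunoglobulin receptor Pigr fell from 1505 ± 418 to 55.7 ± 45.2 CPM (fell by 4.99 on the log2 scale, adjusted p = 0.00152 by limma), Agr2, needed for mucin folding, from 349 ± 115 to 11.7 ± 8.44, the progenitor transcription factor Myb from 88.3 ± 19.2 to 3.71 ± 4.08 and the oxidase Nox1 from 216 ± 94.7 to 9.51 ± 4.56. Angptl2 and Cyp21a1 rose by 4.97 and 4.77 on the log2 scale, and Aqp1 and Hao2 fell by 4.69 and 4.38. Smad4 was 126 ± 7.22 and 152 ± 18.1 CPM (log2 change 0.26, adjusted p = 0.0784 by limma). It passed without replicate L46 of TGFB1 with BMP2 and in the fit over 12 libraries with the line as a block (adjusted p = 0.033 by limma), and its sign turned with total reads as the scaling. Ccl20 was not listed in this table and was not analysed in it.

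Of 21 TGFB targets in colonoids 20 rose and 1 fell (20 and 1 adjusted over the list alone; camera adjusted p = 8.96e-08, and adjusted p = 0.464 with an estimated correlation). Smad7 stood at 13.1 ± 2.93 and 151 ± 47.1 CPM and Pmepa1 at 95.1 ± 19.0 and 853 ± 178. All 25 cell cycle genes fell (25 adjusted over the list alone; camera adjusted p = 4.18e-06, and adjusted p = 0.628 with an estimated correlation). Among them were the replication helicase genes Mcm7 (261 ± 25.7 to 68.1 ± 39.4) and Mcm3 (157 ± 6.73 to 26.6 ± 26.1). Of 14 goblet cell markers 12 fell and 1 rose (12 and 1 adjusted over the list alone; camera adjusted p = 3.92e-05, and adjusted p = 0.464 with an estimated correlation). They included the secretory lineage factors Atoh1 (18.2 ± 5.67 to 0.522 ± 0.123) and Spdef (29.6 ± 8.98 to 2.28 ± 0.816). Of 11 mesenchymal transition and matrix genes 9 rose and 0 fell (10 and 0 adjusted over the list alone; camera adjusted p = 0.00064, and adjusted p = 0.464 with an estimated correlation). Of 19 junction and keratin genes 15 rose and 2 fell (15 and 2 adjusted over the list alone; camera adjusted p = 0.00143, and adjusted p = 0.509 with an estimated correlation). The claudin Cldn4 went from 522 ± 126 to 3024 ± 688 and Cldn15 from 203 ± 21.7 to 11.9 ± 9.53.

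Cytokine, interferon and stress genes moved higher in the same colonoids. Of 16 other cytokines 9 rose and 1 fell (9 and 1 adjusted over the list alone; camera adjusted p = 0.0067, and adjusted p = 0.464 with an estimated correlation). Il34 stood at 5.61 ± 0.797 and 34.9 ± 4.53 CPM. Of 17 interferon-stimulated genes 10 rose and 2 fell (11 and 2 adjusted over the list alone; 0.0278, and adjusted p = 0.628 with an estimated correlation). Irf8 fell from 54.9 ± 5.37 to 12.1 ± 5.91. Of 14 stress genes 10 rose and 1 fell (11 and 1 adjusted over the list alone; 0.0067, and adjusted p = 0.464 with an estimated correlation). Fos went from 61.8 ± 12.3 to 306 ± 60.1. Among the other colonoid lists, camera made no call for NF-kB and TNF targets (8 and 5 of 27, adjusted p = 0.793), chemokines (4 and 3 of 9, 0.901), BMP targets (3 and 1 of 7, 0.377) or antigen presentation (3 and 2 of 12, 0.949). It made none for epithelial defence (0 and 3 of 12, 0.382), absorptive markers (5 and 4 of 18, 0.98), stem cell and Wnt genes (8 and 8 of 21, 0.992) or enteroendocrine markers (1 and 1 of 12, 0.949). Single members moved in them: Id1 rose from 22.8 ± 5.62 to 132 ± 63.1 CPM, Cd44 from 180 ± 24.6 to 598 ± 108 and Cxcl16 from 90.0 ± 22.8 to 278 ± 38.5, and Lrig1 fell from 333 ± 8.68 to 54.2 ± 35.4. Of the lists too small to test, 2 of 3 tuft cell markers rose, 3 of 4 stromal and muscle markers rose and 1 fell, 1 of 1 lymphocyte, 1 of 4 myeloid and 2 of 3 pan-leukocyte markers fell, and 0 of 2 endothelial markers passed the test by limma. The test called 6596 of 11633 genes, 3262 higher and 3334 lower, against 1996 higher and 5010 lower with total listed reads as the only scaling, where the median gene shifted by -0.263 on the log2 scale.

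Colonoids given all 3 ligands were compared with those given TNF alone. Ccl20 fell from 21.0 ± 12.8 to 1.45 ± 0.140 CPM (fell by 2.96 on the log2 scale, SE 0.47, adjusted p = 0.00387 by limma with Benjamini-Hochberg adjustment), from 21.9, 33.4 and 7.80 to 1.29, 1.48 and 1.56 in lines L42, L43 and L46. Arg1 rose from 1.27 ± 0.551 to 108 ± 65.3 CPM, Onecut2 from 3.11 ± 1.53 to 147 ± 85.7 and the retinaldehyde dehydrogenase Aldh1a3 from 32.7 ± 6.10 to 930 ± 402, while Alox12, Angptl2 and Acsbg1 rose by 4.90, 4.76 and 4.75 on the log2 scale. Agr2 fell from 316 ± 100 to 7.30 ± 2.93 CPM, Pigr from 1586 ± 504 to 45.5 ± 27.0, the alcohol dehydrogenase Adh1 from 820 ± 519 to 31.5 ± 4.80 and Cldn15 from 164 ± 14.6 to 6.57 ± 4.99, and Myb and Aqp1 fell by 4.53 and 4.43. C3 fell from 38.8 ± 32.2 to 0.981 ± 0.339 CPM, whereas Tnfaip3 rose further from 147 ± 15.3 to 264 ± 20.3. Smad4 was 123 ± 5.84 and 155 ± 19.9 CPM (log2 change 0.33, adjusted p = 0.0475 by limma and 0.0565 with the line as a block), a call lost in every leave-out (adjusted p by limma of up to 0.148) but that of all 3 ligands L46. With total reads as the scaling it was 0.07 (adjusted p = 0.565 by limma), and in the fit over 12 libraries with the line as a block 0.34 (adjusted p = 0.0101 by limma).

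All 20 TGFB targets rose under TNF in colonoids (20 adjusted over the list alone; camera adjusted p = 8.54e-09, and adjusted p = 0.517 with an estimated correlation). Smad7 stood at 15.7 ± 4.61 and 154 ± 45.8 CPM. All 25 cell cycle genes fell (25 adjusted over the list alone; 3.65e-06, and adjusted p = 0.699 with an estimated correlation). Goblet cell markers fell in 12 of 14 cases while 1 rose (12 and 1 adjusted over the list alone; 2.6e-05, and adjusted p = 0.517 with an estimated correlation). Tff3 stood at 138 ± 51.4 and 15.9 ± 1.77. Of 10 mesenchymal transition and matrix genes 8 rose and 0 fell (9 and 0 adjusted over the list alone; 0.00101, and adjusted p = 0.517 with an estimated correlation). Of 19 junction and keratin genes 14 rose and 2 fell (14 and 2 adjusted over the list alone; 0.00195, and adjusted p = 0.517 with an estimated correlation). Of 17 other cytokines 9 rose and 2 fell (9 and 2 adjusted over the list alone; 0.0491, 0.0562 with the line as a block, and adjusted p = 0.517 with an estimated correlation), a call lost without TNF L43 or all 3 ligands L46 (up to 0.0899). Of 14 stress genes 8 rose and 1 fell (8 and 1 adjusted over the list alone; 0.0204, and adjusted p = 0.517 with an estimated correlation), lost without all 3 ligands L46 (0.0622). Of the remaining lists under TNF, camera did not call NF-kB and TNF targets (8 and 9 of 27, adjusted p = 0.871), chemokines (4 and 6 of 13, 0.822), BMP targets (3 and 1 of 7, 0.5), interferon-stimulated genes (8 and 3 of 18, 0.18) or antigen presentation (0 and 5 of 12, 0.427). Nor did it call epithelial defence (0 and 4 of 11, 0.0776), absorptive markers (4 and 6 of 18, 0.822), stem cell and Wnt genes (7 and 8 of 21, 0.954) or enteroendocrine markers (1 and 1 of 13, 0.871). Of the lists too small to test, 2 of 4 tuft cell markers and 2 of 3 stromal and muscle markers rose, 1 stromal, 1 of 1 lymphocyte, 2 of 3 pan-leukocyte and 1 of 2 endothelial markers fell, and 0 of 3 myeloid markers passed the test by limma. The test called 6278 of 11595 genes, 3061 higher and 3217 lower, against 1912 higher and 4879 lower with total listed reads as the only scaling, where the median gene shifted by -0.243. Without all 3 ligands L42 the count was 4172.

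No single gene passed the interaction test in colonoids (0 of 11413 by limma with Benjamini-Hochberg adjustment, 84 with an unadjusted p under 0.05; 0 by limma with the line as a block and 1 by DESeq2), and Ccl20 was not among the genes tested. Interferon-stimulated genes moved lower in the interaction (17 genes, camera adjusted p = 1.24e-06, and adjusted p = 0.265 with an estimated correlation). So did 9 chemokines (0.0271, and adjusted p = 0.265 with an estimated correlation), a call lost in 6 leave-outs: TNF L42 or L43, all 3 ligands L42 or L46, TGFB1 with BMP2 L46 and vehicle L46 (up to 0.203). Antigen presentation (12 genes, 0.00057, and adjusted p = 0.265 with an estimated correlation) lost its call without TGFB1 with BMP2 L46 or all 3 ligands L42 (up to 0.092), and epithelial defence (11 genes, 0.000629, and adjusted p = 0.305 with an estimated correlation) without TGFB1 with BMP2 L43, TNF L43 or all 3 ligands L42 (up to 0.118). Absorptive colonocyte markers (18 genes, 0.00168, and adjusted p = 0.462 with an estimated correlation) lost it without TGFB1 with BMP2 L43, TNF L43, all 3 ligands L46 or vehicle L46 (up to 0.483). Leave-outs of this interaction had no block for the line, so lost calls can come from unequal lines. With the line as a block BMP targets (7 genes, 0.0976 to 0.0411) and stress genes (14 genes, 0.0536 to 0.0411) passed camera as well, but neither did with the block and an estimated correlation (adjusted p = 0.457 for each). The remaining interaction lists had no camera call: NF-kB and TNF targets (27 genes, adjusted p = 0.139), other cytokines (14, 0.0976), TGFB targets (19, 0.531), and goblet cell markers (14, 0.999). Nor had stem cell and Wnt genes (21, 0.531), enteroendocrine markers (12, 0.634), cell cycle genes (25, 0.531), mesenchymal transition and matrix genes (10, 0.377) or junction and keratin genes (19, 0.373). Smad4 had an interaction of 0.08 on the log2 scale (adjusted p = 1 by limma).

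**Figure D2:**
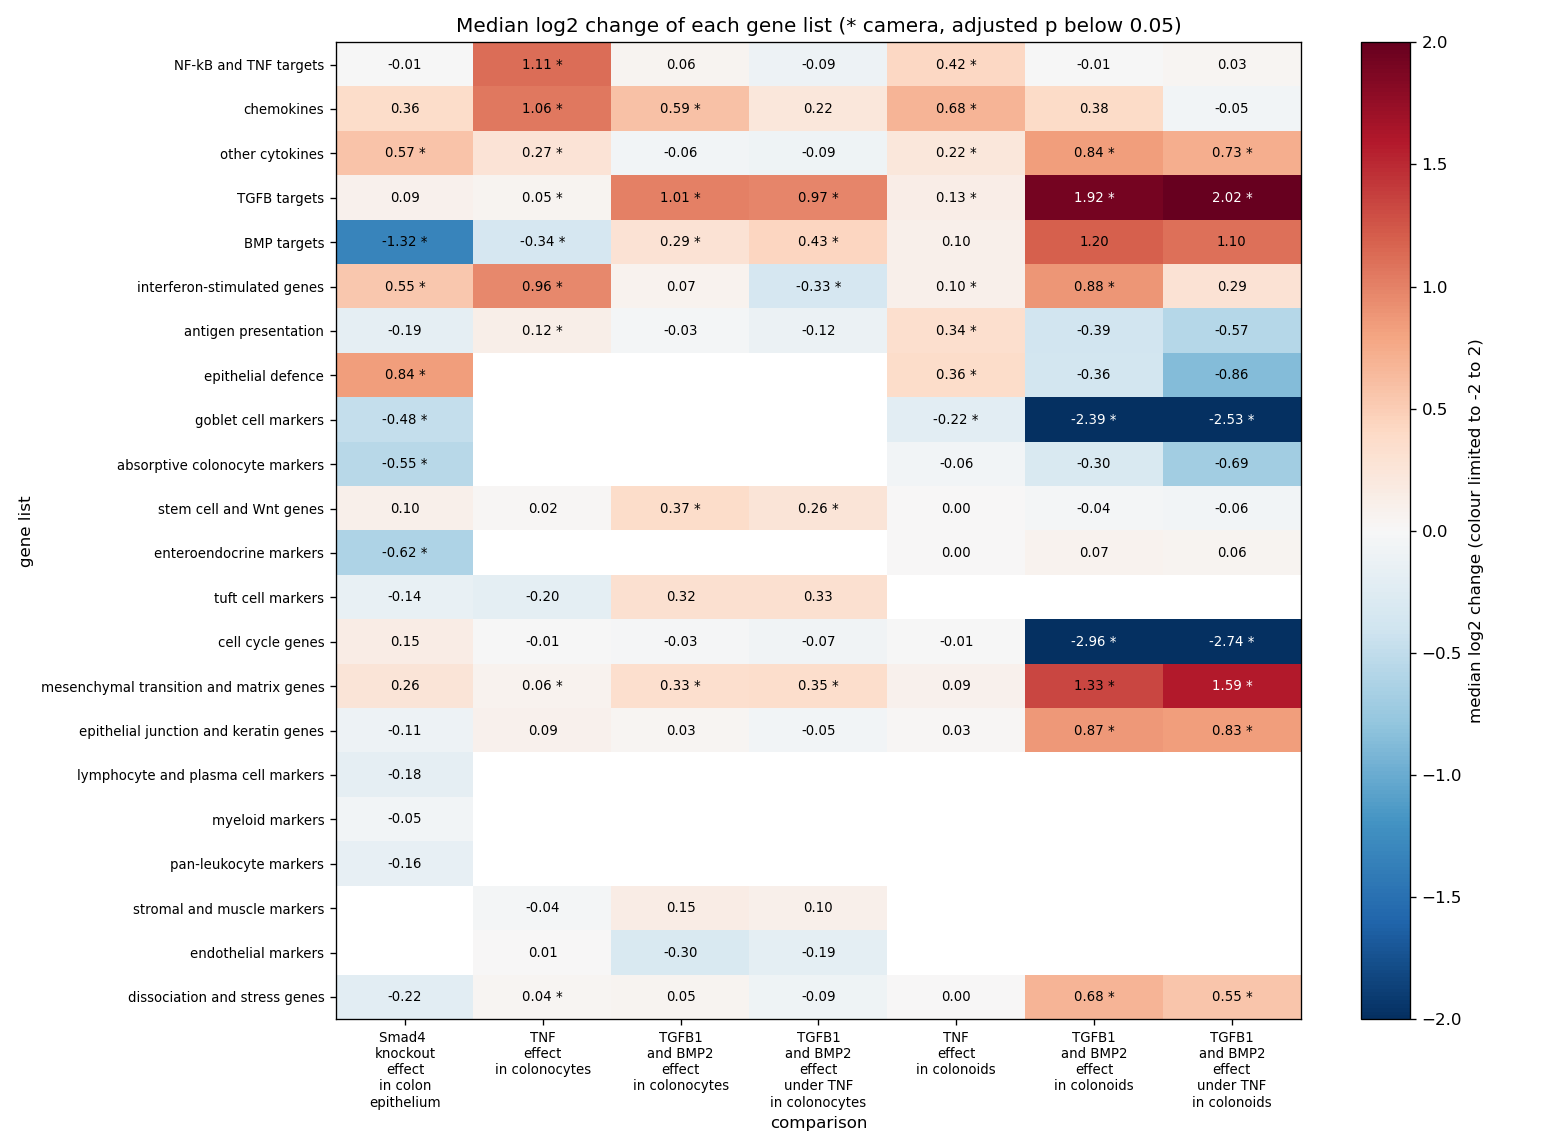
Median log2 change (colour, limited to -2 and 2) of the 22 gene lists in the 7 comparisons; an asterisk marks a camera adjusted p under 0.05, and lists with fewer than 5 genes measured are blank.

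Genes called in both systems were compared, though control colonocytes were low in junction and keratin genes. With TNF, 4 genes were higher in both, Nfkbia, Tnfaip3, Birc3 and Tapbp, against 0.355 by chance (p = 0.000233, Fisher's exact test), and 0 were lower in both. The 4 were named for the small count, after their values were seen. Without vehicle L42 or without TNF L42 the p was 0.0868. With the replicate block in both systems 158 genes were higher in both against 35.9 (p = 5.28e-68, Fisher's exact test) and 20 lower in both against 10.7 (p = 0.00572). With TGFB1 and BMP2, 797 genes were higher in both against 460 by chance (p = 4.53e-84, Fisher's exact test), and 403 were lower in both against 382.8 (p = 0.196). Of the rest, 238 were higher in colonocytes and lower in colonoids against 453.6 (p = 1.2e-42, Fisher's exact test), and 355 were lower in colonocytes and higher in colonoids against 388.2 (p = 0.0335). The p for genes lower in both was 0.00119 without vehicle L43, 0.00946 without TGFB1 with BMP2 L42 and 0.0024 without TGFB1 with BMP2 L46. Log2 changes correlated across genes at 0.375 (Pearson; Spearman 0.189) for TNF and 0.268 (Spearman 0.208) for TGFB1 with BMP2.

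Genes higher in the Smad4 knockout were compared with the TGFB1 and BMP2 effect. In colonoids 803 genes were higher in both against 601 by chance (p = 4.79e-26, Fisher's exact test) and 779 lower in both against 643.7 (p = 2.73e-12). Another 473 were higher in the knockout and lower with the ligands against 654.7 (p = 3.8e-22, Fisher's exact test) and 451 the reverse against 590.9 (p = 1.51e-14). In colonocytes 405 genes were higher in both against 307.6 by chance (p = 5.49e-11, Fisher's exact test) and 221 lower in both against 249.6 (p = 0.0317). There 187 genes were lower in the knockout and higher with the ligands against 293.3 (p = 6.91e-15, Fisher's exact test) and 321 the reverse against 261.8 (p = 1.73e-05). The last p was 0.513 without colonocyte control replicate 3. These opposite pairings were also counted with a change of at least 1 log2 in both. There the ratio to chance of lower in the knockout and higher with the ligands turned from 0.638 to 4.06 in colonocytes (p = 0.00165, Fisher's exact test) and went from 0.763 to 1.16 in colonoids (p = 0.417). The ratio of the reverse pairing went from 1.23 to 0 in colonocytes (p = 1, Fisher's exact test) and from 0.722 to 1.15 in colonoids (p = 0.499). Only the ratio of 4.06 had a p under 0.05 by Fisher's exact test at this threshold. The Pearson correlation across genes was 0.102 (Spearman 0.129) with the colonoids and 0.021 (Spearman 0.0469) with the colonocytes.

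The TGFB1 and BMP2 responses with and without TNF, which share no library, were compared within each system. In colonoids both responses come from the same lines. Deviations of a line correlated at 0.852, 0.896 and 0.940 between TGFB1 with BMP2 and all 3 ligands. Same-number colonocyte libraries of these groups correlated at 0.211, 0.218 and 0.426. The responses are therefore not independent, and shared deviations can raise the overlaps and correlations below. In colonocytes 1520 genes were higher and 1212 lower in both settings, against 300.4 and 256.8 by chance, and 1 was called in opposite directions. In colonoids 2826 were higher and 2865 lower in both against 858.3 and 912.5, and 0 in opposite directions. The Pearson correlation across genes was 0.929 (Spearman 0.854) in colonocytes and 0.982 (Spearman 0.978) in colonoids. Genes that TNF raised in one culture system were also tested in the other. The 460 genes raised in colonocytes had a median log2 change of 0.32 with TGFB1 and BMP2 under TNF in colonoids, 212 of them higher and 74 lower (camera p = 4.81e-06, and p = 0.0945 with an estimated correlation). Limited to a rise of at least 1 log2 the list held 51 genes, 16 higher and 16 lower, and the call was lost with a camera p of 0.568. With the replicate block it held 1205 genes with a median of 0.12, 492 higher and 295 lower (camera p = 0.0194, and p = 0.138 with an estimated correlation). Leave-outs gave medians of 0.188 to 0.370. The lowest came without colonocyte control replicate 3, with 700 genes, 278 higher and 171 lower (camera p = 0.00671, and p = 0.14 with an estimated correlation). The 8 genes raised in colonoids had a median of 0.06 in colonocytes, 2 higher (Lix1l and Nav2) and 2 lower (Tmem176a and Tapbp), with a camera p of 0.564; these were named for the small count, after their values were seen. With the replicate block the list held 314 genes, 114 higher and 110 lower, with a median of -0.01 and a camera p of 0.408.

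**Figure D3:**
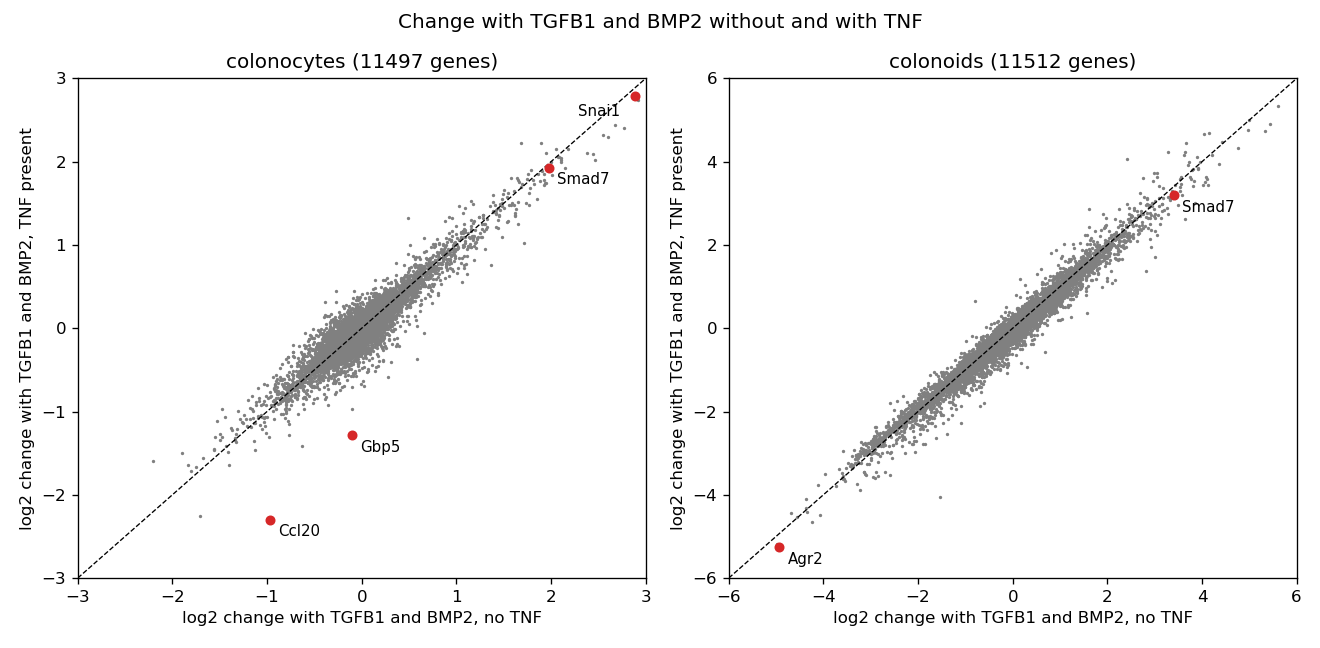
Log2 change with TGFB1 and BMP2 without TNF (x axis) and under TNF (y axis), 1 point per gene, for 11497 genes in colonocytes and 11512 in colonoids. The dashed line marks equal change.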

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

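All 7 technical tests below were chosen after the result they test had been seen. The bounds of the pseudocount, scaling and stromal level tests were reworded, and the test for other cell types was divided and given other genes, after their values had been seen; the 9 tests by exchanging samples were planned before.

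In the knockout, 35.4% of the Smad4 reads of the controls remained. Cells that kept Smad4 or reads from the part of the transcript that was not removed are possible causes, and which exons were removed is not given in the sources used here. Of the genes measured, 18 stood at a lower share of control than Smad4 by more than 2 added SE, among them Id3 at 2.77%. This argues against unchanged control-like cells as the only source, though cells that kept Smad4 beside changed neighbours could differ from controls too. All 10 pan-leukocyte markers were listed. Their median in the knockout libraries was 6.51 CPM or less, below the bound of 50, which argues against leukocytes. The lymphocyte and myeloid medians were 5.11 and 0.828 CPM or less. Only 12 of 20 lymphocyte and 8 of 16 myeloid markers were listed and the others counted as 0, which holds these medians low, so they cannot decide. Vim and Col4a1, abundant in fibroblasts and endothelial cells, stood at 11.7 CPM or less (bound 50), which argues against these; the pair was chosen after its values were seen, because only 2 of 16 stromal and 1 of 12 endothelial markers were listed. Reads of a shortened transcript may also explain the Smad4 reads left, which reads per exon would test.

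Ccl20 had an interaction of -1.336 in colonocytes. With a pseudocount of 0.1 it was -0.8231, with an adjusted p of 0.999 by limma, so it could not be told apart from an effect of the low values without TNF. With total reads as the scaling it was -1.358, so scaling is not likely to be its source. On a ratio scale a larger fall under TNF stays open, as edgeR on the recovered reads gave an interaction of -0.64 that did not pass (adjusted p = 0.999).

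Control colonocytes held high stromal and low epithelial transcripts; the tables were normalized separately, and the difference between systems was not tested. Their junction and keratin genes stood at 0.0466% or less of the colonoid level (median over members, genes not listed counted as 0, bound 50), which argues against a minority of stromal cells in an epithelial culture. Their stromal list median was at least 42.4 CPM, or 42.4 times a colonoid level of 0 that was set to 1 because most members were not listed there (bound 10). Krt8 stood at 1.17 CPM against 3531 in colonoids, listed in both, so shallow libraries are not likely to be the source. A mesenchymal state of the line could give this pattern, as might a culture made up mostly of fibroblasts, and neither was tested.

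Exchanging samples between groups put the real split first in 1 of 10 splits in all 7 comparisons, where 10 splits cannot give a share under 0.05; the real counts were 4611, 728, 3513, 3694, 16, 6596 and 6278 and the highest other count was 0. For the interactions the share of splits with a count as high as the real one was 3 of 100 in colonocytes (real 1, highest other 5438). Exchanging the TGFB1 and BMP2 labels there also broke up the effect of these ligands (3513 and 3694 genes) or could move it into the interaction. The share therefore cannot tell whether the 1 call arose by chance. In colonoids the share was 100 of 100 (highest other 8395). A real count of 0 gives this whatever the splits call, so the test tells nothing there either.

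The lists that differed with TNF by camera with Benjamini-Hochberg adjustment were, in colonocytes, NF-kB and TNF targets (4.12e-09), chemokines (2.39e-11), TGFB targets (0.0222), interferon-stimulated genes (9.29e-22) and antigen presentation (0.00848). With an estimated correlation the adjusted p was 0.157, 0.00882, 0.411, 0.157 and 0.157 in this order, so that only chemokines held. In colonoids they were chemokines (0.0271), interferon-stimulated genes (1.24e-06), antigen presentation (0.000571), epithelial defence (0.00063) and absorptive colonocyte markers (0.00168). With an estimated correlation it was 0.265, 0.265, 0.265, 0.305 and 0.462, so that none held, and only interferon-stimulated genes kept the preset call in every leave-out.

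Several named genes had log2 changes of opposite sign with TGFB1 and BMP2 in the culture systems, a difference that was not tested. In colonocytes Mcm6 did not pass limma (adjusted p = 0.111, and 0.115 under TNF), nor did Jun under TNF (0.169). Log2 changes in colonocytes and colonoids were 2.776 and -1.2 for Adamts15, 0.8012 and -0.8278 for Ripk2, 0.6855 and -2.473 for Creb3l1, -0.5034 and 0.7277 for Galnt12, 0.3763 and -0.5444 for Slc26a2, 0.2513 and -2.213 for Mcm4, 0.2952 and -1.658 for Rrm2, and -0.7814 and 1.815 for Krt19. They were -0.9335 and 1.21 for Dusp1, -0.4359 and 1.333 for Il1rn, -0.3308 and 0.9914 for Tgfa, 0.3329 and -2.776 for Lrig1, 0.1005 and -1.983 for Mcm6, and 0.8965 and -1.916 for Pdgfrb. Under TNF they were 2.407 and -1.939 for Adamts15, 0.8256 and -2.462 for Creb3l1, -0.528 and 0.6951 for Galnt12, 0.3077 and -0.7161 for Slc26a2, 0.2657 and -1.906 for Mcm4, 0.3233 and -1.725 for Rrm2, and -0.6908 and 1.607 for Krt19. The others under TNF were -0.9954 and 1.172 for Dusp1, 0.4434 and -1.597 for Atoh8, 0.2018 and -2.84 for Lrig1, 0.0991 and -1.569 for Mcm6, 0.7127 and -1.96 for Pdgfrb, and -0.0883 and 1.611 for Jun.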

How the results depend on the processing

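Total listed reads as scaling, a fit over 12 libraries and the overlaps and lists under them were chosen after seeing the data. So were some settings with edgeR or DESeq2 size factors. Most others were planned. The cause was not tested for any change given here.

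For TNF in colonocytes (728) the count was 2356 with the replicate block, 2486 with edgeR and the block and 1636 in the 12-library fit with the block. For TNF in colonoids (16) it was 718 and 733 with the block (limma and edgeR), 116 with DESeq2, 7 in the 12-library fit and 41 there with the block. For the interaction in colonocytes (1) it was 0 with a pseudocount of 0.1, 30 with the block, 2 with total reads as the scaling, 0 with edgeR, 0 with edgeR and DESeq2 size factors, 27 with edgeR and the block and 13 with DESeq2. For the interaction in colonoids (0) DESeq2 gave 1.

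Leaving out 1 library gave 2709 to 4914 genes for the knockout, 399 to 1216 for TNF in colonocytes, 1 to 8 for TNF in colonoids, 4172 to 7545 for TGFB1 and BMP2 under TNF in colonoids and 0 to 10 for the interaction in colonocytes. Of 461 values of named genes, calls were lost for 15 with total reads as the scaling, 10 with edgeR and 3 with DESeq2. In the 12-library fit, which covers only the comparisons within the cultures, 9 were lost and 340 stayed the same. Over all leave-outs 204 were lost and 2573 stayed the same.

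Among overlaps, the ratio to chance of genes lower with TNF in both systems turned from 0 to 1.795 with edgeR and the block and 1.869 with limma and the block. For TGFB1 and BMP2 the ratio for lower in both went from 1.053 to 1.128 and 1.145 in the same settings. With a change of at least 1 log2, the ratio of the knockout against TGFB1 and BMP2 was 0 (higher and lower) and 4.064 (lower and higher) in colonocytes, and 1.151 and 1.161 in colonoids. Of these only 4.064 had a p under 0.05 by Fisher's exact test. Leave-outs gave 7.405 to 22.52 for genes higher with TNF in both, 1.011 to 1.168 for genes lower with TGFB1 and BMP2 in both and 0.9679 to 1.449 for genes higher in the knockout and lower in colonocytes. The median of the TNF-induced list in colonocytes was -0.00921 with the block and -0.2254 to 0.1486 in leave-outs, and that in colonoids was 0.1729 for a list with a rise of at least 1 log2.

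With the preset correlation the block changed no other list call of the paired fits than those given beside the results. In the colonocyte interaction, which was not taken as paired, it gave other cytokines 0.0484 and BMP targets 0.048. DESeq2 size factors changed 1 call, other cytokines under TNF in colonoids (0.0525). With fry 40 of the 59 calls held; the 19 lost were 7 of 8 for TNF in colonoids, all 5 of the colonoid and 4 of 5 of the colonocyte interaction, and 1 each for the knockout and TGFB1 with BMP2 in colonoids without and with TNF. For TGFB1 with BMP2 in colonocytes fry called 8 lists against 5, and 10 against 5 under TNF.

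Smad4 changes turned sign with total reads as the scaling, to -0.02742 for TNF, -0.0195 for TGFB1 with BMP2 and -0.05328 for the latter under TNF in colonocytes, and from 0.2613 to -0.01523 for TGFB1 with BMP2 in colonoids, where this scaling shifts the median gene by -0.263. Leave-outs gave -0.01914 to 0.03559 for TNF and -0.01094 to 0.07099 for TGFB1 with BMP2 under TNF in colonocytes, and -0.07905 to 0.001943 for TNF in colonoids. For the interactions they gave -0.08069 to 0.0009092 in colonocytes and -0.004841 to 0.1889 in colonoids.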

Other observations

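Levels of untreated cultures are from separately normalized tables, and differences were not tested. In control colonocytes Col1a1 stood at 2157 ± 143 CPM, Col3a1 at 1188 ± 85.4, Sparc at 3149 ± 219 and Dcn at 485 ± 29.9 (n = 3). Krt8 stood at 1.17 ± 0.439 and Cdh1 at 1.15 ± 0.242 there, and at 3531 ± 437 and 1285 CPM in vehicle colonoids.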
